A study of Mus musculus with 17 samples.

How the data were processed

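Whole brains of 17 mice were homogenized, RNA was isolated with a spin column kit, and libraries were made with a bulk form of MARS-seq, which counts the 3′ ends of transcripts, per the labels' protocols. Per the submitters' processing notes, cutadapt (a read trimmer), HTSeq (a read counter) and the mouse build mm10 were used. Their versions and settings, the aligner and the use of molecular identifiers in counting are not given in the sources used here. The samples form 5 groups: Gba-/-;GbaTg (KO, n = 4), Gba+/-;GbaTg (HetTg, n = 3) and Gba+/+ (WT, n = 4) of the chronic model, and CBE-injected and PBS-injected wild-type mice (n = 3 each) of the acute model. Each sample is taken to be 1 mouse; the labels number the samples without naming the animals, so p-values measure the spread between these samples.

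The authors deposited 3 tables, for the chronic model, the acute model and the comparison of adult WT with PBS mice. Per the file headers each table holds raw counts per gene symbol, which were used for all tests. The authors' normalized values, a signal on the scale of counts divided by 1 size factor per library, and their log2 values, named rld, stand beside the counts and entered no test. The deposited log2 fold changes and p-values of the authors' own comparisons, with a mark for genes that passed, were set beside the refit. Another 15 columns, none of them a per-sample measurement, were not mapped and not used. Libraries that appear in more than 1 table had 0 differing counts over the genes shared. The tables hold 14630 genes (chronic), 13669 (acute) and 14247 (age), and the lowest maximum count of any gene is 6 in each. The joint table of all 17 libraries was made from the 13324 genes present in the chronic and acute tables.

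Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, TMM scaling, low-count filter by group with the package's defaults, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). That left 11830 genes in the chronic fit, 10886 in the acute, 11030 in the age and 12150 in the joint fit. The 11 chronic libraries shared 1 fit, from which KO was compared with the mean of both control groups, with HetTg and with WT, and HetTg with WT. CBE and PBS, and WT and PBS, were fitted separately. The difference between the chronic and the acute effect was a contrast in the joint fit. CPM values use TMM-scaled library sizes and were scaled separately in each table. Adjusted p-values in the text come from these fits unless another tool is named.

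Gene lists (33, of cell type markers, pathways and measures of RNA quality) were tested with camera of limma 3.58.1 at its preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and checked with an estimated correlation and with fry. Calls among members were counted over all genes tested and adjusted over the list alone. Overlap of calls was tested with Fisher's exact test, 2-sided. The genes named in the text follow a rule: Gba; in the main comparisons the 10 genes each way with the largest log2 fold change among those called, with a mean of at least 20 counts in the higher group and no overlap between the libraries of both sides, leaving out symbols made of Gm and a number, ending in Rik or holding -ps; up to 4 called members of each list with the smallest p, or up to 2 members where fewer were called; and up to 5 genes each way with the smallest p in the remaining comparisons. Genes named outside it are said to have been chosen after their values were seen. Groupings, tests, lists, this rule and most alternatives were fixed before the data were examined.

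For a gene with 0 counts in a whole group a fold is given as a lower bound, against a floor of 3 counts over the group; with 1 to 3 counts the ratio of normalized counts is given with an exact 95% binomial interval. Intervals and floors cover counting error only. Within groups, chi-square per degree of freedom between libraries ran from 1.98 to 9.28 over 21 pairs, so no library was a copy of another. Gene positions and biotypes are from the GENCODE annotation of the mm10 assembly, matched by symbol (14381 of 14630 symbols in the chronic table).

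Each procedure was tested on simulated counts with 200 genes changed by known folds, drawn from the means and library sizes of the real libraries. Each gene was drawn on its own, without deviations shared between the genes of a library. False calls that such deviations bring are thus not counted in these values. For KO against both controls edgeR recovered 63.3% of genes changed by log2 1 and 94.9% of those changed by log2 2, with 3.73% false calls (11830 genes simulated). The same values were 44.3%, 91.8% and 6.34% for KO against HetTg, 51.5%, 93.9% and 4.05% for KO against WT, and 36.4%, 96.0% and 6.43% for HetTg against WT. They were 76.8%, 100% and 4.44% for the acute comparison (10886 genes), 61.5%, 98.9% and 6.83% for age (11030 genes), and 25.3%, 75.3% and 6.67% for the difference between models (12150 genes).

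Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom, no filter and a stricter filter on low counts, each library left out in turn, the replicate number as a block, age in months as a covariate, other sets of samples in the fit, other control groups, other set tests and other thresholds. After seeing the data, fits without the 3 shallowest libraries and with a smooth trend in GC content and transcript length removed from each library (mgcv 1.9.3) were added. Leaving out the 3 shallowest libraries keeps HetTg replicate 3 as the only HetTg library, so comparisons with HetTg then rest on 1 library. Alternatives planned for normalized values were not needed, since counts were given.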

Results

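Messenger RNA of whole brain homogenates was sequenced in 17 mice of 2 Gaucher disease models on a C57BL/6JOlaHsd background. Gaucher disease follows from loss of glucocerebrosidase, the lysosomal enzyme encoded by Gba. The chronic model comprised 4 Gba-/-;GbaTg mice (KO), with 3 Gba+/-;GbaTg littermates (HetTg) and 4 Gba+/+ littermates (WT) as controls, all given doxycycline for about 4 to 7 months. Ages were 6 to 7.5 months in KO, 6.75 to 8.3 months in HetTg and 6 to 9 months in WT. In the acute model, 3 wild-type mice received conduritol B-epoxide (CBE), an irreversible inhibitor of glucocerebrosidase, and 3 received saline (PBS) from postnatal day 8 to 21, and brains were taken on day 21. Library totals ranged from 562056 to 4048076 counts. HetTg replicates 1 and 2 and WT replicate 4 held 788344, 562056 and 896928 counts, the lowest totals of the chronic model, so that small differences involving these groups were measured least precisely. The acute libraries held 1403541 to 2052882 counts in CBE and 1226133 to 2479832 in PBS.

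Gba, located on chromosome 3 (89202928 to 89208966, mm10), was measured first because the models target its product. In the chronic table its level was 8.06 ± 2.41 CPM (counts scaled to TMM library size; SD, n = 4) in KO, 24.7 ± 2.48 (n = 3) in HetTg and 42.2 ± 7.96 (n = 4) in WT. Each KO library lay below each control library. KO and HetTg mice carry the GbaTg transgene and WT mice do not. Whether transcripts of the transgene or the null allele are counted for Gba was not examined. Against the mean of both control groups the KO level was 3.98-fold lower (log2 fold change -1.99 ± 0.22 SE; edgeR quasi-likelihood test, adjusted p = 0.000107). HetTg and WT differed by -0.78 ± 0.24, which did not pass the test (edgeR, adjusted p = 0.9997; unadjusted p = 0.00545). The transcript was not lowered by CBE, which acts on the enzyme: Gba stood at 69.8 ± 8.20 CPM in CBE and 49.1 ± 2.52 in PBS (n = 3 each), 1.41-fold higher (edgeR, adjusted p = 0.0115). That small rise lost its call without CBE replicate 2 (log2 fold change 0.40, adjusted p = 0.0748), in DESeq2 (adjusted p = 0.0682) and in a fit of all samples (adjusted p = 0.0629).

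**Figure D1:**
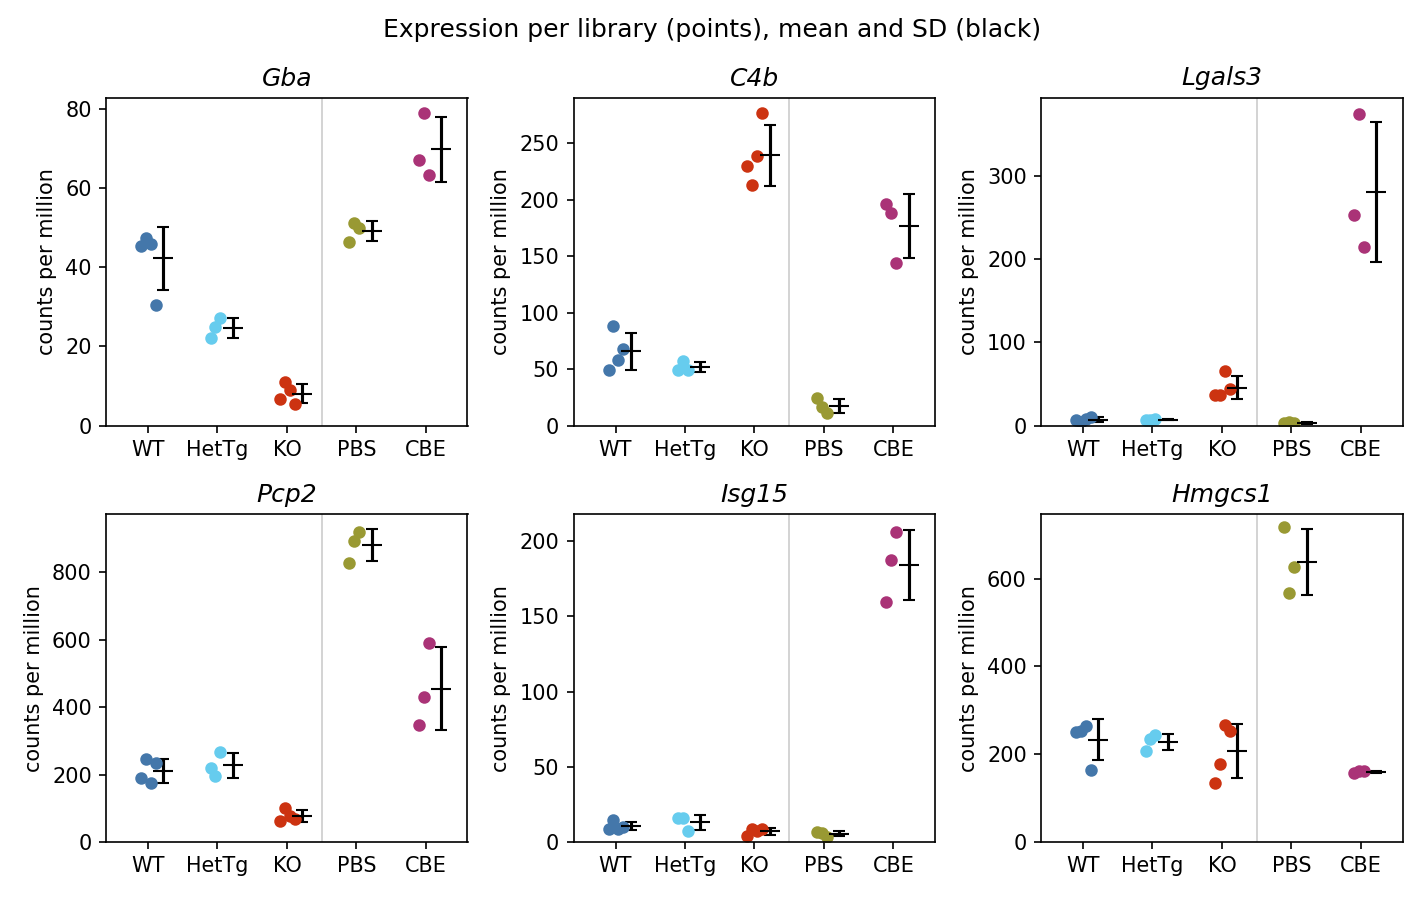
CPM (linear axes from 0) of Gba, C4b, Lgals3, Pcp2, Isg15 and Hmgcs1 in each library (points) of the adult WT, HetTg and KO mice and of the 21-day-old PBS and CBE mice; black marks give the group mean and SD. The chronic and acute tables were scaled separately, so levels are comparable only within each side of the grey line; C4b averaged 240 CPM in KO and 59.9 in the adult controls, and 177 in CBE and 17.5 in PBS.

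The lead question of the chronic model was how the brains of KO mice differ from those of both control groups. Transcripts of disease-associated microglia, reactive astrocytes and complement rose and Purkinje cell transcripts fell in the KO brains. C4b, a complement component, rose from 59.9 ± 14.2 CPM in the 7 controls to 240 ± 27.0 in the 4 KO libraries, 4.11-fold. Serpina3n, an acute-phase protease inhibitor made by reactive astrocytes, rose 4.92-fold, and Lgals3, the galectin of phagocytic microglia, rose 6.65-fold. Pcp2, a Purkinje cell protein, fell from 218 ± 33.8 to 76.8 ± 17.3 CPM, 2.85-fold. In all, 217 of 11830 genes tested passed an adjusted p of 0.05 (edgeR quasi-likelihood test), 132 higher and 85 lower, and 90 of them differed by over 2-fold.

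Among the genes with the largest rise and no overlap between KO and control libraries, Cst7 (an inhibitor of lysosomal cathepsins in microglia) led with a log2 fold change of 4.81 ± 0.49 (edgeR, adjusted p = 7.11e-05). C3, the central complement protein, followed at 3.24 ± 0.35 (adjusted p = 9.33e-05), then Lgals3 at 2.73 ± 0.25 (adjusted p = 1.49e-05). Serpina3n rose by 2.30 ± 0.19 and C4b by 2.04 ± 0.15. Osmr (the oncostatin M receptor) rose by 2.09, Lyz2 (lysozyme) by 1.90 and Apoc1 (an apolipoprotein) by 1.83. Plaur, the urokinase receptor, rose by 2.70 ± 0.65 and Sbno2 by 1.91 ± 0.37 (2.37-fold without KO replicate 4), both with 1 KO library far above the other 3. Among called genes with no overlap between these libraries, the largest falls after Gba were those of Car8 (-1.81 ± 0.26), Ighm, the immunoglobulin M heavy chain (-1.52 ± 0.19), Pcp2 (-1.51 ± 0.17), Arhgef33 (-1.41 ± 0.23) and Homer3 (-1.20 ± 0.16). Myl4 (-1.15), Pcp4 (-1.12), Hs3st2 (-1.07) and Kctd21 (-1.05) followed.

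Of 24 disease-associated microglia genes tested, 7 rose and none fell over all genes tested, and 18 rose when adjusted over the list alone. Cst7, Lgals3, Lyz2 and the phagocyte glycoprotein Cd68 (3.37-fold) were among them. The list's median log2 fold change was 0.56, and camera placed it above other genes (adjusted p = 2.55e-21, and adjusted p = 0.0194 with an estimated correlation). Of 20 reactive astrocyte genes, 8 rose and none fell (13 adjusted over the list alone), with a median of 0.98 (camera adjusted p = 7.77e-21, and adjusted p = 0.0194 with an estimated correlation). Gfap, the astrocyte intermediate filament, rose 3.54-fold and Vim, vimentin, 1.89-fold. Without the 3 shallowest libraries, an alternative chosen after seeing the data that keeps 1 HetTg library, Vim had a log2 fold change of 0.75. Of 11 complement genes, 6 rose (8 adjusted over the list alone), among them C1qc at 2.05-fold, with a median of 0.57 (camera adjusted p = 1.61e-15, and adjusted p = 0.0201 with an estimated correlation). C4b shares most of its sequence with C4a, so its counts may include reads of that copy.

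Of 24 Purkinje cell genes, 8 fell and none rose; 15 fell and 2 rose when adjusted over the list alone. The median was -0.53 (camera adjusted p = 1.63e-13, and adjusted p = 0.0201 with an estimated correlation). Car8, which binds the inositol trisphosphate receptor, Homer3, a postsynaptic scaffold, and Pcp2 and Pcp4 were the clearest. The series title speaks of Purkinje cell loss, so the choice of this list was not independent of the study. Pvalb, the calcium buffer of Purkinje and fast-spiking interneurons, fell 2.07-fold, whereas the inhibitory neuron list it belongs to was not called (1 higher and 3 lower adjusted over the list alone; median 0.07, mean 0.02, camera direction down, adjusted p = 0.778). Nefh, a neurofilament of large axons, fell 1.63-fold; the 28 pan-neuronal genes had a median of -0.04 (camera adjusted p = 0.0746). None of the 19 cerebellar granule cell genes was called (median 0.25, camera adjusted p = 0.178), and the 17 excitatory neuron genes had a median of -0.03 (camera adjusted p = 0.601).

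The lysosome list, which holds glucocerebrosidase's neighbours in the organelle, moved little: 3 of 56 genes rose (Cd68, Ctsz at 1.62-fold and Man2b1 at 1.53-fold), also when adjusted over the list alone, with a median of 0.08 (camera adjusted p = 0.025, and adjusted p = 0.235 with an estimated correlation). Of 42 glycosphingolipid genes only Gba was called over all genes, and 1 rose and 2 fell when adjusted over the list alone (median 0.01, mean -0.08, camera direction down, adjusted p = 0.432). Of 10 cytokine and chemokine genes, Cxcl10 (3.88-fold), Ccl6 (3.83-fold) and Cxcl16 (2.84-fold) rose, and 5 rose and 2 fell when adjusted over the list alone (camera adjusted p = 0.00484, and adjusted p = 0.279 with an estimated correlation). Of 19 antigen presentation genes H2-Ab1 rose 1.78-fold, alone also when adjusted over the list alone (median 0.29, camera adjusted p = 0.00949, and adjusted p = 0.356 with an estimated correlation). None of 22 type I interferon genes was called over all genes (median -0.09, mean 0.02, camera direction down, adjusted p = 0.862); Slfn2 alone passed when adjusted over the list alone (log2 fold change 1.79, adjusted p = 0.0509 over all genes).

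Further lists shifted as sets with few single calls. None of 26 oligodendrocyte and myelin genes was called (1 fell when adjusted over the list alone, Gjc2 at -1.15 ± 0.29), with a median of -0.36 (camera adjusted p = 1.74e-05, and adjusted p = 0.167 with an estimated correlation). Of 24 cholesterol biosynthesis genes Ebp, the sterol isomerase, fell 1.70-fold (2 fell adjusted over the list alone; median -0.31; camera adjusted p = 0.000651, and adjusted p = 0.165 with an estimated correlation). Of 16 glucocorticoid and stress response genes, Lcn2 (lipocalin, 6.01-fold; 3.64-fold without KO replicate 4 and 13.9-fold without HetTg replicate 3), Per1 and Nfkbia rose, and 8 rose when adjusted over the list alone (median 0.76; camera adjusted p = 5.18e-07, and adjusted p = 0.149 with an estimated correlation). Of 14 meningeal and matrix genes Col6a1 (2.92-fold) and Fmod (2.89-fold) rose, and 5 when adjusted over the list alone (camera adjusted p = 0.000801, and adjusted p = 0.356 with an estimated correlation). Atf4 and Calr, of the unfolded protein and integrated stress response, fell 1.71-fold and 1.64-fold, with no call for their list (camera adjusted p = 0.0585).

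Measures of library quality moved beside these groups. The 9 mitochondrially encoded transcripts had a median of -0.85 in KO (0 called over all genes, 3 lower adjusted over the list alone; mt-Nd2 -1.57 ± 0.49; camera adjusted p = 0.000836, and adjusted p = 0.356 with an estimated correlation). The mitochondrial share of counts was 0.137 to 0.173% in the KO libraries. It was higher in WT replicates 3 and 4 (0.315% and 0.613%) and HetTg replicates 1 and 2 (0.327% and 0.348%), and lower in WT replicates 1 and 2 (0.118% and 0.132%) and HetTg replicate 3 (0.111%), so 4 of the 7 controls set the direction. The 77 genes matched by a ribosomal protein name pattern had a median of -0.22 (camera adjusted p = 0.00303, and adjusted p = 0.441 with an estimated correlation), and 1 of them, the pseudogene Rps3a3, rose, a call lost with the controls taken as 1 group (log2 fold change 2.18, adjusted p = 0.122). The 5 erythrocyte transcripts had a median of -0.83 (0 called; camera adjusted p = 0.0558). The remaining lists were not called in camera: homeostatic microglia (median -0.07, adjusted p = 0.766), astrocyte (-0.08, 0.273), oligodendrocyte precursor (-0.13, 0.0599), endothelial and mural (-0.03, 0.432), choroid plexus and ependyma (0.05 with a mean of -0.02, 0.981), infiltrating leukocyte (0.38, 0.291), hypothalamus and pituitary (-0.06, 0.534), immediate early (0.16, 0.123), apoptosis, necroptosis and p53 (0.07, 0.5), oxidative stress and iron (0.12, 0.754), proliferation (-0.01, 0.427) and immature neuron (-0.03 with a mean of 0.01, 0.873).

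Single libraries weighed on the number of genes called. It was 112, 84, 85 and 73 without KO replicate 1, 2, 3 or 4. It was 142 and 106 without HetTg replicate 2 or 3, and 104 without WT replicate 3. Without the 3 shallowest libraries HetTg replicate 3 stands alone for its group, and Sbno2 had a log2 fold change of 1.69. Deviations from the group means correlated across groups at 0.391 (KO replicate 4 and HetTg replicate 1), 0.428 (HetTg replicate 1 and WT replicate 4) and 0.312 (KO replicate 4 and WT replicate 4), and at 0.401 (KO replicate 2 and WT replicate 1) and 0.371 (HetTg replicate 3 and WT replicate 1). Of 41 called genes named here 25 kept their call with each single library left out, among them C4b, Serpina3n, Lgals3, Cst7, C3, Gfap, Cd68, Pcp2, Car8 and Homer3. Hs3st2 lost its call without KO replicate 4 (edgeR, adjusted p = 0.0599), Myl4 without KO replicate 1 or 2 (up to 0.0579) and Fmod without KO replicate 1 or HetTg replicate 3 (up to 0.0575). Calls lost in several such fits were those of Atf4 (4 of 11 fits, adjusted p up to 0.0781), Lcn2 (5 of 11, 0.103), Calr (6 of 11, 0.0957), Man2b1 (7 of 11, 0.111), Ctsz (8 of 11, 0.132), Ebp (8 of 11, 0.0969), Cxcl16 (9 of 11, 0.118), Per1 (9 of 11, 0.108), Kctd21 (9 of 11, 0.115), Nfkbia (10 of 11, 0.134) and H2-Ab1 (10 of 11, 0.164). Plaur lost it in 7 of the 8 fits that tested it (up to 0.0844) and Ccl6 in 4 of 5 (up to 0.0904).

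**Figure D2:**
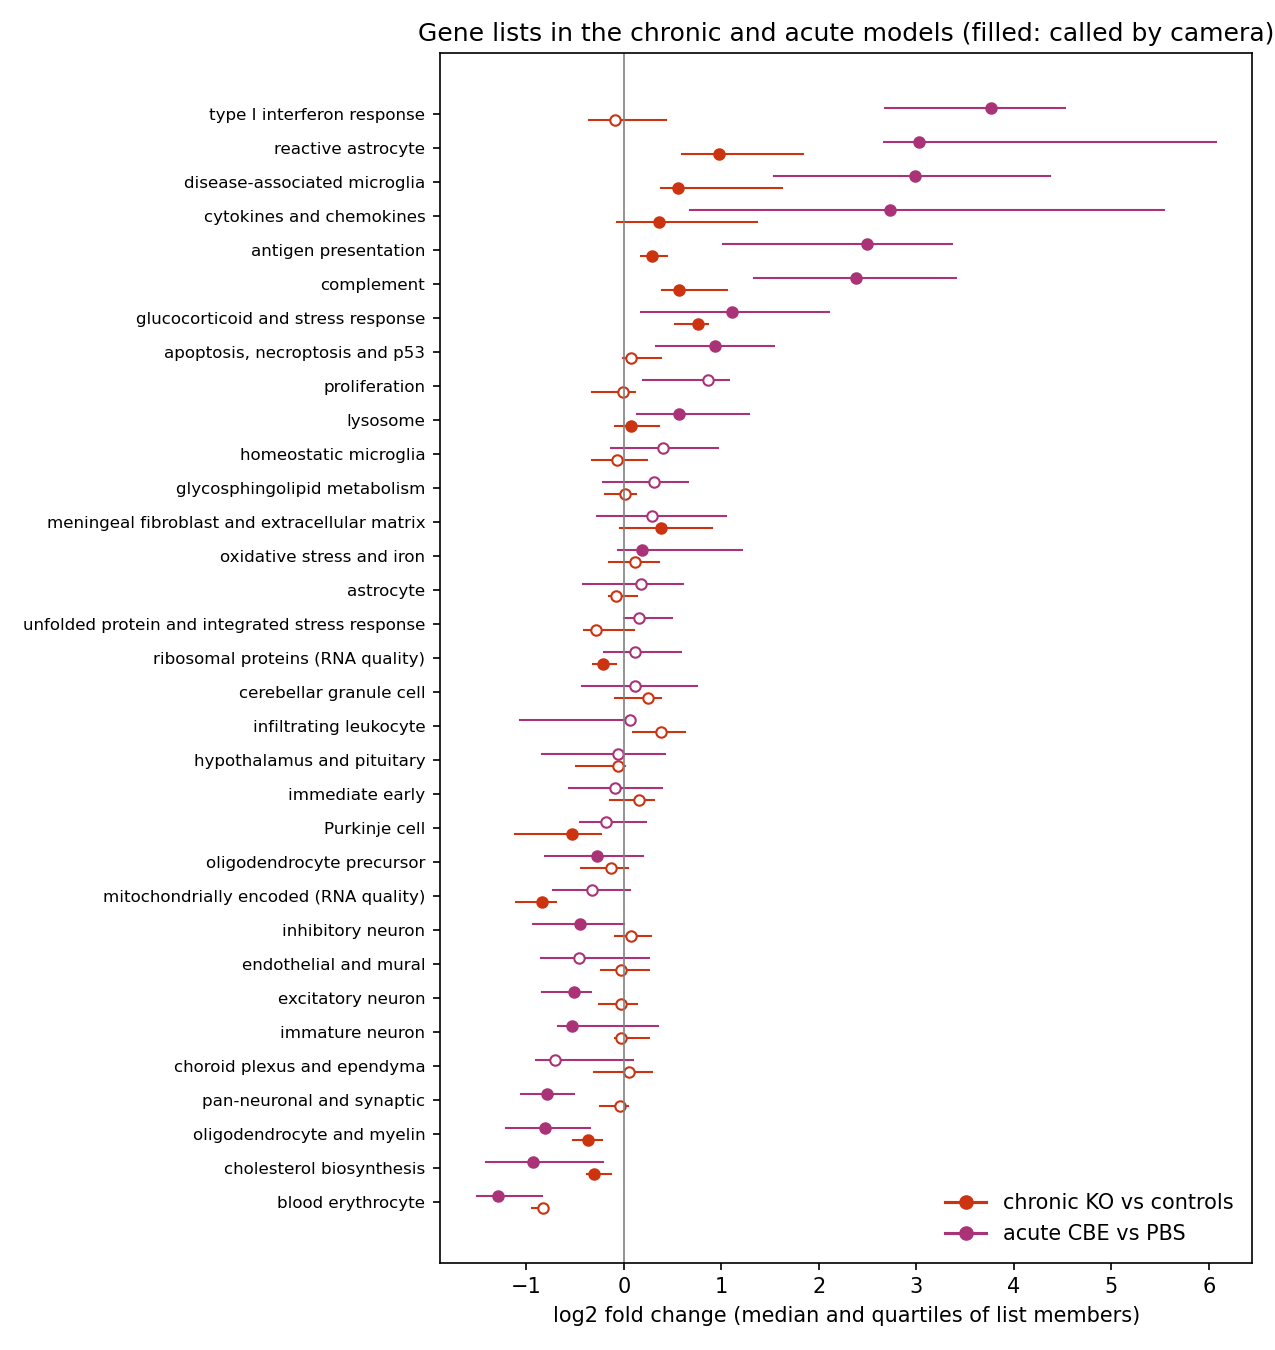
Median log2 fold change (points) and quartiles (lines) of the members of 33 gene lists in KO against both chronic controls (red) and in CBE against PBS (purple); filled points mark lists called by camera with its preset correlation. The reactive astrocyte list lies at 0.98 and 3.03, the type I interferon list at -0.09 and 3.77, and the Purkinje cell list at -0.53 and -0.18. The members tested can differ between both fits (22 and 33 for the interferon list).

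The comparison of KO with HetTg matched the animals for the transgene. The same kinds of transcript led it. C3 was 16.5-fold, Lgals3 6.33-fold, C4b 4.67-fold, Serpina3n 4.29-fold and Gfap 3.62-fold higher in KO, and Car8 was 3.62-fold, Pcp2 2.97-fold, Ighm 2.82-fold and Homer3 2.30-fold lower. Gba was 3.04-fold lower (edgeR, adjusted p = 0.0133). In all 23 genes were called, 15 higher and 8 lower, and 1232 had an unadjusted p under 0.05. Camera called 13 lists, of which the disease-associated microglia, complement, reactive astrocyte and Purkinje lists kept their call (each adjusted p = 0.017 with an estimated correlation). Without HetTg replicate 3, the deepest HetTg library, 5 genes were called, and Lgals3 (adjusted p = 0.0544), C3 (25.4-fold, 0.0628), Gfap (0.0544), Homer3 (0.0891), Car8 (0.213) and Gba (0.187) kept their direction but not their call. The calls of Gba and Car8 were also lost without KO replicate 1 or 3, that of Gba in a fit of only KO and HetTg (adjusted p = 0.0529), and 13 genes were called without KO replicate 3. Without the 3 shallowest libraries, which leaves HetTg replicate 3 alone in its group, the log2 fold change was 1.79 for Serpina3n and -1.14 for Ighm. The authors' deposited table gives an adjusted p under 0.05 to 60 genes here, 38 of them with its pass mark.

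Against WT, KO brains showed 230 called genes (108 higher, 122 lower; edgeR). Serpina3n was 5.64-fold, Lgals3 6.99-fold and C4b 3.61-fold higher, and Gba was 5.21-fold, Ighm 2.91-fold, Pcp2 2.74-fold, Homer3 2.29-fold and Pvalb 2.16-fold lower. The smallest p belonged to Rps3a3, a processed pseudogene of a ribosomal protein gene on chromosome 13 (108670603 to 108671397), with a log2 fold change of 6.18 ± 0.38 (adjusted p = 1.87e-07). The noncoding transcript 4933439C10Rik was 3.41-fold higher. Each of these 10 genes kept its call with every single library left out. Camera called 11 lists, of which the disease-associated microglia and reactive astrocyte lists kept their call (each adjusted p = 0.0427 with an estimated correlation). The complement (adjusted p = 0.0558 with an estimated correlation) and Purkinje lists (0.0545) lost theirs against WT. The count itself was 68 without WT replicate 3, 117 and 131 without WT replicate 2 or 4, and 137, 87, 92 and 110 without KO replicate 1, 2, 3 or 4. The authors' deposited table gives an adjusted p under 0.05 to 393 genes and its pass mark to 131.

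HetTg and WT, the background comparison between control groups, differed in 1 gene of 11830 by edgeR, and 522 had an unadjusted p under 0.05; DESeq2 called 2. The authors' deposited table gives an adjusted p under 0.05 to 6 genes after a further correction, per its header, and to 2 before it, with the pass mark on 5. That gene was Rps3a3, at 84.5 ± 8.66 CPM in HetTg (n = 3) and 2.13 ± 0.20 in WT (n = 4), a log2 fold change of 5.32 ± 0.41 (adjusted p = 5.50e-06). KO held 155 ± 63.6 CPM. Rps3a1, the protein-coding source gene of that pseudogene on chromosome 3 (86137940 to 86142702), went the other way. It stood at 242 ± 57.0 CPM in WT, 65.6 ± 56.3 in HetTg and 30.2 ± 34.3 in KO. Against WT its log2 fold change was -3.05 ± 0.75 in KO (edgeR, adjusted p = 0.0478). In HetTg it was -1.71 ± 0.79, which was not called (edgeR, adjusted p = 0.9997). Rps3a1 made up 99.0 to 99.3% of the counts of both in the WT libraries, with exact binomial 95% intervals within 97.3 to 99.9%. The share was 0.219%, 24.4%, 0.803% and 49.8% in the KO libraries and 48.2%, 7.69% and 56.3% in HetTg. Reads were not examined, and reads of a copy may be counted for its source gene, so the level of each is uncertain. Camera also placed the oligodendrocyte and myelin list (median -0.19, adjusted p = 0.0389) and the ribosomal list (median -0.24, adjusted p = 6.78e-09) lower in HetTg, each with adjusted p = 0.863 with an estimated correlation.

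**Figure D3:**
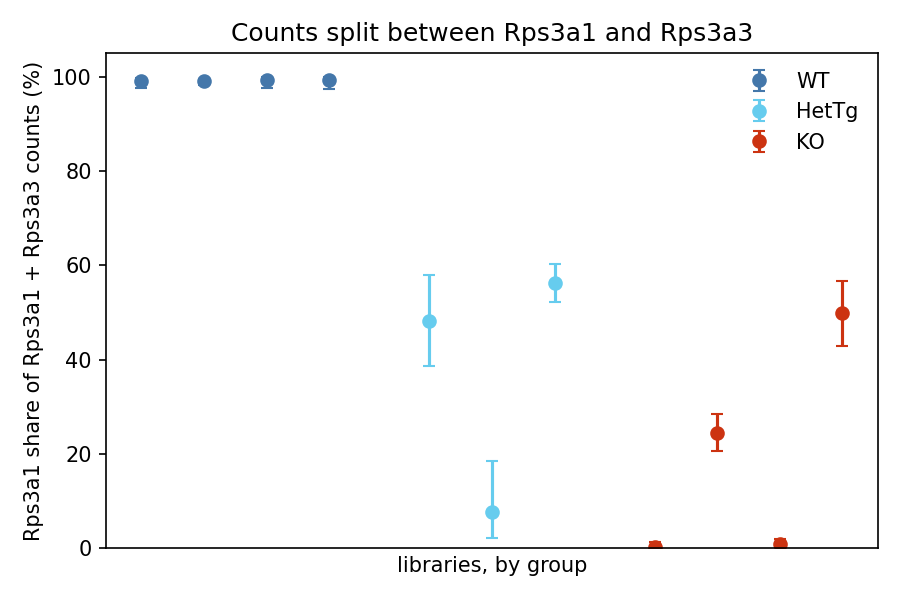
Share of Rps3a1 in the summed counts of Rps3a1 and Rps3a3 (percent, axis from 0) in each chronic library, by group, with exact binomial 95% intervals that cover counting error only. WT libraries lie at 99.0 to 99.3%, while HetTg and KO libraries lie between 0.219 and 56.3%.

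The acute comparison asked what inhibition of the enzyme from postnatal day 8 to 21 does to the brain. Interferon, disease-associated microglia, reactive astrocyte and antigen presentation transcripts rose and transcripts of cholesterol synthesis, myelin and neurons were lower in CBE. Of these lists the interferon (adjusted p = 0.0717 with an estimated correlation), myelin and pan-neuronal ones (0.0997 each) lost their call in that form of camera. Isg15, an interferon-induced ubiquitin-like protein, rose from 5.37 ± 1.57 to 184 ± 23.3 CPM (n = 3 each), 32.2-fold. Serpina3n rose 46.8-fold, Lgals3 72.7-fold and H2-K1, a class I histocompatibility antigen, 20.5-fold. Hmgcs1, which makes the HMG-CoA of sterol synthesis, fell from 637 ± 75.3 to 160 ± 2.27 CPM, 3.98-fold. By edgeR 5281 of 10886 genes tested were called, 2739 higher and 2542 lower, 1907 of them by over 2-fold. With 3 mice a side, other groupings of the same mice are too few for a permutation p under 0.05, and PBS and CBE mice came from 1 experiment.

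Several of the largest rises started from nearly no counts in PBS. Lilrb4a, Ccl2, Cd300lf, Lilr4b, Milr1 and Tgm1 had 0 counts in all PBS libraries. Against a floor of 3 counts over the PBS group they were at least 123-fold, 74.9-fold, 42.6-fold, 38.3-fold, 24.0-fold and 23.6-fold higher in CBE. Lilrb4a and Lilr4b are near-identical immune receptor genes whose reads may be split. Cst7 had 2 counts in PBS and 559 in CBE, a ratio of 279 (exact binomial 95% interval 76.9 to 2309, counting error only), and Ptx3, a pattern recognition protein, had 3 and 462, a ratio of 154 (52.3 to 748). Their fitted log2 fold changes moved from 7.91 to 10.54 and 7.18 (Cst7) without PBS replicate 1 or 2, and from 7.03 to 7.67 and 6.42 (Ptx3) without PBS replicate 2 or CBE replicate 3. Cxcl10, a chemokine, reached 549 ± 236 CPM (log2 fold change 9.08 ± 0.41; 10.39 without PBS replicate 2) and Lcn2 460 ± 119 CPM (8.02 ± 0.29). The largest falls by the rule for named genes were smaller: Cyp51, a sterol demethylase (-2.29 ± 0.29; -3.07 without CBE replicate 3), Dnaic1 (-2.15 ± 0.29), Aqp6 (-2.14), Enpp6 (-2.13), Lyplal1 (-2.10), Tnnt1 (-2.07), the splicing factor U2af2 (-2.05 ± 0.15), Phospho1 (-1.99), Hdac9 (4.01-fold lower) and Cox4i2 (3.99-fold lower).

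All 33 type I interferon genes tested rose, over all genes and adjusted over the list alone, with a median log2 fold change of 3.77 (camera adjusted p = 2.07e-52, and adjusted p = 0.0717 with an estimated correlation). Only 22 genes of this list were tested in the chronic fit, and 22 in the age fit, which holds the same PBS libraries. Members near 0 counts in PBS could pass the filter through CBE alone. The count and the median thus lean towards genes that rise. The same can hold for the microglia, astrocyte and cytokine lists below. Irf7, the transcription factor of that response, rose 23.0-fold. Of 28 disease-associated microglia genes 26 rose and none fell (also 26 adjusted over the list alone); the median was 2.99, also with 3 members at 0 counts in PBS set to their bound (camera adjusted p = 7.74e-49, and adjusted p = 0.0219 with an estimated correlation). Spp1, osteopontin, rose 20.1-fold and Cd68 11.1-fold. Of 23 reactive astrocyte genes 22 rose (22 adjusted over the list alone), with a median of 3.03, also with Tgm1 at its bound (camera adjusted p = 2.47e-47, and adjusted p = 0.0218 with an estimated correlation); Vim rose 7.70-fold. Of 20 antigen presentation genes 16 rose and none fell (16 adjusted over the list alone; median 2.49; camera adjusted p = 2.84e-22, and adjusted p = 0.0169 with an estimated correlation). Ctss, the protease that processes the invariant chain, rose 11.8-fold. Of 14 cytokine and chemokine genes 10 rose and 2 fell (11 and 2 adjusted over the list alone), with Ccl5 up 28.1-fold and a median of 2.73, also with Ccl2 at its bound (camera adjusted p = 4.6e-11, and adjusted p = 0.0258 with an estimated correlation). Of 12 complement genes 10 rose and 1 fell, also adjusted over the list alone, with C1qc at 5.35-fold and C1qa at 5.07-fold (median 2.38; camera adjusted p = 1.27e-14, and adjusted p = 0.0608 with an estimated correlation).

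Of 56 lysosome genes 31 rose and 5 fell (33 and 5 adjusted over the list alone), with a median of 0.57 (camera adjusted p = 8.8e-12, and adjusted p = 0.043 with an estimated correlation); the protease Ctsl rose 7.75-fold. Of 40 glycosphingolipid genes 14 rose and 8 fell (17 and 8 adjusted over the list alone), without a call for the list (median 0.31, camera adjusted p = 0.240). Of 24 cholesterol biosynthesis genes 15 fell and none rose, also adjusted over the list alone, with a median of -0.93 (camera adjusted p = 1.28e-07, and adjusted p = 0.043 with an estimated correlation). Dhcr24, which catalyses the last reduction to cholesterol, fell 3.60-fold. Glucocorticoid and stress response genes rose in 11 of 16 cases and fell in 2, also adjusted over the list alone, with Sgk1 at 7.32-fold and Fkbp5 at 7.41-fold (median 1.11; camera adjusted p = 6.42e-07, and adjusted p = 0.160 with an estimated correlation). Of 15 apoptosis, necroptosis and p53 genes 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.93; camera adjusted p = 0.000311, and adjusted p = 0.0997 with an estimated correlation). Zbp1, the nucleic acid sensor of necroptosis, went from 2 to 206 counts (ratio 103, 28.1 to 855; fitted log2 fold change 6.43, and 9.00 without PBS replicate 2), and Tnfrsf1a rose 6.20-fold. Of 15 oxidative stress and iron genes 7 rose and 1 fell, also adjusted over the list alone (median 0.18; camera adjusted p = 0.00924, and adjusted p = 0.156 with an estimated correlation). Hmox1, heme oxygenase, rose 11.9-fold, while of the metallothioneins Mt2 rose 4.09-fold and Mt3 fell 2.15-fold.

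Of 23 oligodendrocyte and myelin genes 16 fell and none rose, also adjusted over the list alone, with a median of -0.81 (camera adjusted p = 1.27e-08, and adjusted p = 0.0997 with an estimated correlation). The myelin proteins Mog and Mag fell 2.87-fold and 2.86-fold. Of 19 oligodendrocyte precursor genes 7 fell and 3 rose, also adjusted over the list alone, with Sox10 2.87-fold and Olig1 2.45-fold lower (median -0.28; camera adjusted p = 0.0227, and adjusted p = 0.167 with an estimated correlation). Of 28 pan-neuronal genes 22 fell and 4 rose, also adjusted over the list alone, with a median of -0.79 (camera adjusted p = 1.85e-08, and adjusted p = 0.0997 with an estimated correlation). The synaptic vesicle genes Syn1 and Syp fell 2.83-fold and 2.84-fold and the enolase Eno2 2.47-fold. Of 16 excitatory neuron genes 10 fell and 1 rose, also adjusted over the list alone; Slc17a7, a vesicular glutamate transporter, fell 2.17-fold and Nrgn 1.96-fold (camera adjusted p = 0.00924, and adjusted p = 0.189 with an estimated correlation). Of 20 inhibitory neuron genes 10 fell and 2 rose (12 and 2 adjusted over the list alone). Sst fell 2.19-fold and Gad1 2.05-fold, but the transporter Slc6a1 rose 2.28-fold (camera adjusted p = 0.00924, and adjusted p = 0.189 with an estimated correlation). Of 18 immature neuron genes 11 fell and 2 rose (11 and 3 adjusted over the list alone), with Marcksl1 2.24-fold lower (median -0.53; camera adjusted p = 0.00924, and adjusted p = 0.160 with an estimated correlation).

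All 5 erythrocyte transcripts tested fell in CBE, also adjusted over the list alone, with Hbb-bt 3.46-fold and Hba-a2 2.85-fold lower (median -1.29; camera adjusted p = 0.000183, and adjusted p = 0.0997 with an estimated correlation); Hba-a2 has a near-identical copy. The lists not called by camera were Purkinje cell (6 of 24 lower, 3 higher; median -0.18, adjusted p = 0.222), cerebellar granule cell (0.12, 0.791), homeostatic microglia (0.40, 0.123), astrocyte (0.18, 0.309), endothelial and mural (-0.46, 0.282), meningeal and matrix (0.29, 0.359), choroid plexus and ependyma (-0.70, 0.222), infiltrating leukocyte (0.06 with camera direction down, 0.549), hypothalamus and pituitary (-0.06, 0.605), immediate early (-0.09 with a mean of 0.05, 0.624), unfolded protein response (0.16, 0.282), proliferation (0.86, 0.222), ribosomal (0.12, 0.222) and mitochondrial (-0.32, 0.359). Of 58 called genes named for CBE, 57 kept their call with each single library left out, Gba being the exception. The authors' deposited table gives an adjusted p under 0.05 to 4164 genes and its pass mark to 1836.

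The deposited tables also compare adult WT mice with the 21-day-old PBS mice, as a measure of age. In the adult brains 16 of 25 myelin and 9 of 17 immature neuron transcripts were lower, and 12 of 18 antigen presentation transcripts were higher (each list adjusted p = 0.310 with an estimated correlation). Mog stood at 112 ± 7.30 CPM in the adults (n = 4) and 727 ± 124 in the young mice (n = 3), 6.45-fold lower, and Mag was 3.38-fold lower. Marcksl1, which regulates actin in growing neurons, was 8.11-fold lower, and H2-K1 4.05-fold higher. By edgeR 4429 of 11030 genes tested were called, 2350 higher and 2079 lower, 2043 of them by over 2-fold. Doxycycline was given to the adults and PBS injections to the young mice, so neither can be separated from age here. Gba differed by -0.24 ± 0.19 (edgeR, adjusted p = 0.328).

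The largest rises from PBS to adult WT mice by the rule for named genes were those of Hoxb8 and Hoxb6, posterior patterning genes. Hoxb8 had 155 counts against 2, a ratio of 44.9 (exact binomial 95% interval 12.2 to 374, counting error only). Hoxb6 had a log2 fold change of 5.10 ± 0.59 (edgeR, adjusted p = 2.57e-05). Whether age or another difference between these mice and samples brought these rises was not tested. Without PBS replicate 1 the fitted log2 fold change of Hoxb8 moved from 5.30 to 8.17 (24.0-fold without PBS replicate 2), that of Hoxb6 to 5.74 and that of Hoxa5 to 4.31. Hspa1b, a heat shock protein with a near-identical copy (3.67 ± 0.50), Pak3 (3.55), Rasgrf2 (3.42), Hipk2 (3.31 ± 0.31), Hoxa5 (3.29), Acsl4 (3.08), mt-Nd5 (3.07 ± 0.56) and Ifit3b (2.98) followed. The largest falls by that rule were those of AC164612.2 (-3.28 ± 0.27), Tmem86b (-3.25), Marcksl1 (-3.02 ± 0.27), Tbata (-2.99), Mybpc3 (-2.97), AI480526 (-2.90), Ybx2 (-2.83), Leng8 (-2.82), Syne4 (-2.72) and Cnpy1 (-2.72). All 29 called genes named here kept their call with each single library left out.

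Camera called 6 lists for age, none of them with an estimated correlation. Of 25 oligodendrocyte and myelin genes 16 were lower and 4 higher, also adjusted over the list alone (median -0.73; adjusted p = 1.86e-06, and adjusted p = 0.310 with an estimated correlation). Of 18 antigen presentation genes 12 were higher, also adjusted over the list alone, with Ctss at 2.47-fold (median 0.92; adjusted p = 7.01e-05, and adjusted p = 0.310 with an estimated correlation). Of 17 immature neuron genes 9 were lower, also adjusted over the list alone, Dpysl5 by 1.97-fold (median -0.54; adjusted p = 0.00560, and adjusted p = 0.310 with an estimated correlation). Of 23 cholesterol biosynthesis genes 9 were lower (10 adjusted over the list alone), Hmgcs1 by 2.82-fold and Dhcr24 by 1.99-fold (adjusted p = 0.0176, and adjusted p = 0.401 with an estimated correlation). All 3 infiltrating leukocyte genes tested were lower, also adjusted over the list alone, the T cell receptor gene Trbc2 by 3.40-fold (adjusted p = 0.0499, and adjusted p = 0.401 with an estimated correlation). Of 9 mitochondrially encoded transcripts 7 were higher (8 adjusted over the list alone), the ribosomal mt-Rnr2 by 5.72-fold (3.22-fold without WT replicate 4; median 1.89; adjusted p = 0.0111, and adjusted p = 0.542 with an estimated correlation). The mitochondrial share of counts was 0.084 to 0.096% in PBS and 0.118% and 0.132% in WT replicates 1 and 2. It was 0.315% and 0.613% in WT replicates 3 and 4, which thus stood furthest above PBS. The authors' deposited table gives an adjusted p under 0.05 to 3876 genes and its pass mark to 1924.

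Whether the chronic and acute models differ was tested as the difference of their effects (KO minus both controls, less CBE minus PBS) in 1 fit of all 17 libraries. The interferon and antigen presentation responses of the acute model were the clearest difference. Isg15 had a chronic effect lower than the acute one by a log2 difference of -5.63 ± 0.40 (edgeR, adjusted p = 4.40e-09), Irf7 by -5.17 ± 0.39 (adjusted p = 1.09e-08) and H2-K1 by -3.99 ± 0.20 (adjusted p = 9.47e-12). Gba differed by -2.47 ± 0.28 (adjusted p = 2.66e-06). In all 2841 of 12150 genes differed, 1494 with a higher and 1347 with a lower chronic effect. The models also differ in age, drug and injection, so the test compares 2 experiments and not the disease course alone.

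Among the genes with the largest negative difference were Cxcl10 (-7.07 ± 0.84), Zbp1 (-6.93), Lilrb4a (-6.57), Cd300lf (-6.55), Ccl2 (-6.43), Phf11d (-6.25), Ifit3b (-5.70), Lcn2 (-5.50) and H2-Q7 (-5.37), an antigen gene with close copies. Lilrb4a, Ccl2 and Cd300lf had 0 counts in PBS, so their fitted differences depend on the prior count. The largest positive differences by the rule for named genes were those of Rps3a3 (3.68 ± 0.84; a pseudogene that the rule, which goes by the form of the symbol, does not leave out), U2af2 (2.85 ± 0.31), Lrrc32 (2.79), Ybx2 (2.78), Myh7b (2.59), Atoh7 (2.55), Nol3 (2.52), Dnaic1 (2.51), Efcab12 (2.47) and Fndc9 (2.38). Of 32 called genes named here 28 kept their call with each single library left out. The largest adjusted p was 1 for Lilrb4a, without HetTg replicate 3 (-5.04) or WT replicate 2 (-4.93), and 1 for Cd300lf without HetTg replicate 3 (-5.02). It was 0.134 for Ccl2 without WT replicate 2 (-5.65) and 0.0816 for Lrrc32 without PBS replicate 1. The call of Lrrc32 was also lost with a correction for GC content and length, chosen after seeing the data (adjusted p = 0.0541). Cd300lf, Ccl2 and Lrrc32 also lost their call without PBS replicate 1 or 2, Ccl2 and Lrrc32 without HetTg replicate 3 and Lrrc32 without CBE replicate 1. Without KO replicate 4 the difference was -7.86 for Zbp1, -7.30 for Ccl2, -8.22 for Cd300lf, -6.22 for Lcn2 and 1.85 for Lrrc32. It was -4.25 for Lcn2 without HetTg replicate 3, -6.21 and -4.65 for H2-Q7 without PBS replicate 1 or 2, and -8.44 for Cxcl10 and -9.73 for Zbp1 without PBS replicate 2. With the chronic effect taken against HetTg only, the difference of Rps3a3 was 1.02 (adjusted p = 0.392), and the calls of Ccl2 (0.0580) and Cd300lf (0.0710) were lost too. Against WT only, those of Lcn2 (adjusted p = 0.0676), Ccl2 (0.0519) and Cd300lf (0.0542) were lost.

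Camera called 16 lists for this difference, 6 of them also with an estimated correlation. Of 31 type I interferon genes 28 had a lower chronic effect (29 adjusted over the list alone; median -3.25; adjusted p = 1.15e-38, and adjusted p = 0.000998 with an estimated correlation). The same direction was seen in 18 of 27 disease-associated microglia genes (19 adjusted over the list alone; Spp1 -3.86, and adjusted p = 0.00294 with an estimated correlation), in 17 of 24 reactive astrocyte genes (20 adjusted over the list alone; Serpina3n -3.23, Vim -2.01, and adjusted p = 0.00653 with an estimated correlation) and in 14 of 20 antigen presentation genes (14 lower and 1 higher adjusted over the list alone; Ctss -3.13, and adjusted p = 0.000998 with an estimated correlation). Of 57 lysosome genes 22 had a lower and 2 a higher chronic effect (24 and 2 adjusted over the list alone; Ctsl -2.51, and adjusted p = 0.00653 with an estimated correlation). Of 28 pan-neuronal genes 18 had a higher and 1 a lower chronic effect (18 and 2 adjusted over the list alone; Syn1 1.75, Eno2 1.17, and adjusted p = 0.00653 with an estimated correlation). Cholesterol biosynthesis (8 of 24 higher, Hmgcs1 1.86; camera adjusted p = 0.000451) and complement (7 of 12 lower and 1 higher, C1qa -1.76; camera adjusted p = 9.13e-06) were called with the preset correlation, each with adjusted p = 0.0583 with an estimated correlation. The remaining called lists were cytokine (adjusted p = 0.163 with an estimated correlation), excitatory and inhibitory neuron (0.101 each), apoptosis (0.0583), unfolded protein response and immature neuron (0.200 each), myelin (0.375) and ribosomal (0.482). The Purkinje list had a lower chronic effect by a median of -0.40 without a call (camera adjusted p = 0.0750).

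The calls of both models were compared over the 10638 genes tested in both, which share no library. Genes higher in both numbered 63, where 31.3 were expected for independent lists (odds ratio 3.05, Fisher's exact test, 2-sided, p = 1.15e-09). C4b, Serpina3n, Lgals3, Cst7, C3, Cd68, Gfap, Lyz2, C1qc, Vim, Osmr, Cxcl10 and Apoc1 were among them. Genes lower in both numbered 38, where 19.5 were expected (odds ratio 2.79, Fisher's exact test, p = 1e-05), with Pcp2, Ighm, Pvalb and Nefh among them. At a threshold of 0.01 for both calls, 3 genes were lower in both where 1.73 were expected, which did not pass (Fisher's exact test, p = 0.392). These tests take genes as independent, although genes vary together, so their p-values do not measure the spread between mice. Another 27 genes higher in the chronic model were lower in the acute one, and 8 lower in the chronic model were higher in the acute one, Gba among the latter. Across all genes tested in both, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.245 and a Spearman correlation of 0.117.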

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

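The correction for GC content and length was chosen after the results were seen; the outcomes that would count for or against each of the other tests were written down before the tests were run, although the patterns were noticed in the same data. The difference between the chronic and acute effect was tested directly, and 2841 genes and 16 gene lists passed, 6 of the lists also with an estimated correlation. A lower chronic effect was found for interferon-induced and related genes, Isg15 (log2 difference -5.63), Ifit3b (-5.70), Irf7 (-5.17), Zbp1 (-6.93) and Phf11d (-6.25), and for the antigen presentation genes H2-K1 (-3.99), H2-Q7 (-5.37) and Ctss (-3.13). Chemokine, microglial and astrocyte genes followed: Cxcl10 (-7.07), Ccl2 (-6.43), Lilrb4a (-6.57), Cd300lf (-6.55), Lcn2 (-5.50), Spp1 (-3.86), Serpina3n (-3.23), Ctsl (-2.51), Vim (-2.01) and C1qa (-1.76). Gba, the gene disrupted in KO, differed by -2.47. A higher chronic effect was found for Rps3a3 (3.68), U2af2 (2.85), Lrrc32 (2.79), Ybx2 (2.78), Myh7b (2.59), Atoh7 (2.55), Nol3 (2.52), Dnaic1 (2.51), Efcab12 (2.47), Fndc9 (2.38), Hmgcs1 (1.86), Syn1 (1.75) and Eno2 (1.17). Some of these calls did not hold: without single libraries the adjusted p reached 1 for Lilrb4a and Cd300lf, 0.134 for Ccl2 (all 3 with 0 counts in PBS) and 0.0816 for Lrrc32. It was 0.0541 for Lrrc32 with the GC content and length correction, 0.392 for Rps3a3 with the chronic effect against HetTg only, and 0.0676 for Lcn2 with it against WT only.

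Of 125 sets of 4 values tested for 1 library far from the others, 8 had one, where chance gives about 1 in 20. In KO replicate 4, Sbno2 stood at 117 CPM (others 25.6 to 39.4), Plaur at 51.2 (4.34 to 7.49) and Lcn2 at 67.9 (14.5 to 22.9), while Hs3st2 stood at 16.7 (26.9 to 27.1). Fmod stood at 145 CPM in KO replicate 1 (others 52.1 to 53.7). In WT replicate 4, which held 896928 counts, Gba stood at 30.4 CPM (others 45.4 to 47.4) and Hmgcs1 at 163 (251 to 264), while the value of Rps3a3 (2.43, others 2.02 to 2.04) is 2 counts and too few to set it apart.

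Purkinje cell genes had a median log2 fold change of -0.53 in KO against both controls (bootstrap 95% interval -0.86 to -0.35, 24 genes). The bootstrap intervals here resample genes, which vary together, and do not measure the spread between mice. By the median deviation of these genes each KO library lay below each control library. KO replicate 2 (-0.0753) lay close to HetTg replicate 2 (0.0470), the other KO libraries at -0.318 to -0.548. A smaller share of cerebellum in the KO homogenates would lower genes particular to granule cells as well. The granule cell list had a median of 0.25 (-0.06 to 0.38, 19 genes), which by the outcome written beforehand goes against that share. Slc17a7, Reln and Calb2 of this list also stand in the lists of other neurons. The list's first quartile was -0.095, however, still above -0.267, the median that such a share would have called for. Granule cell deviations were 0.037 to 0.317 in the KO libraries and -0.275 to 0.099 in the controls. For the genes of this list, these values argue against a smaller share of cerebellum as the whole cause. How far its other members are expressed outside the cerebellum was not tested. The low depth of the HetTg libraries is argued against by the median against WT, which was 89.9% of that against HetTg. Loss of Purkinje cells and lower expression per cell, both of which the genotype could bring, remain open. They were not tested, since homogenates hold no cell counts.

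Rps3a3 counts were near absent in WT and high in both groups with the Gba null allele. Rps3a1 was lower in both, called against WT in KO (edgeR, adjusted p = 0.0478) but not in HetTg (0.9997). Rps3a1 lies 3.07 Mb from Gba, so a candidate explanation is a linked strain variant that moves reads between the gene and its pseudogene copy. The summed level of both genes differed between KO and WT by -0.39 on the log2 scale (95% interval -0.87 to 0.09), which neither requires nor excludes this. Between HetTg and WT it differed by -0.64 ± 0.25 SE, a fall that an exchange of reads without loss would not give. The shallow HetTg replicates 1 and 2 held 146 and 92.4 CPM, from 112 and 52 counts. HetTg replicate 3 held 212 CPM, within the 196 to 324 CPM of the WT libraries. The fall between HetTg and WT and the mixed shares within KO and HetTg are open. Of 198 tested genes within 10 Mb of Gba, 1.01% were called in KO against controls (Gm16740 and Tlr2, named after their values were seen) and 1.85% of the other genes (odds ratio 0.543, 0.0649 to 2.01), so other variants of that region cannot be told apart from none.

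PBS libraries stood apart both from CBE and from adult WT libraries. After removal of a trend in GC content and length, which moved genes of low and high GC by medians of -0.33 and 0.42, the number of genes called between CBE and PBS was 90.6% of that before, with 4057 of the 5281 genes called both times, which argues against that trend as the whole cause. More nuclear RNA in the PBS libraries would lower nuclear long noncoding RNAs in CBE; their median was 0.14 (-0.56 to 1.44, 6 RNAs) with Malat1 (1.21), Neat1 (1.67) and Meg3 (0.35) called higher and Mirg (-0.98) called lower, and this explanation cannot be told apart with so few. In adult WT against PBS, Meg3 (-1.06), Miat (-1.73), Snhg11 (-1.54) and Mirg (-2) were called lower, as it would have, while Malat1 (0.61) and Neat1 (0.24) were not called. The treatment and age, which the design names, remain open.

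Other groupings of the same samples were fitted for each count of called genes. For KO against both controls, 3 of 100 drawn splits gave as many genes as the real one (217, itself included). That share is under the 0.05 set beforehand, but 100 drawn splits are too few to place it firmly there. The count of genes therefore does not exclude chance. The highest other split gave 667 genes, which points to a structure of the samples beyond genotype. That split set KO replicate 4, HetTg replicate 1 and WT replicates 2 and 4 in the place of KO, and 3 of these 4 deviated from their group means alike (correlations of 0.391, 0.428 and 0.312 between KO replicate 4, HetTg replicate 1 and WT replicate 4). The real split gave the most genes for KO against HetTg (1 of 35 splits, real 23, highest other 1) and KO against WT (1 of 35, real 230, highest other 0). The same held for age (1 of 35, real 4429, highest other 418). These shares are under the 0.05 set beforehand. However, 1 of 35 is the lowest share that these splits can give, and it was not adjusted over the comparisons. Chance is thus less likely there but not excluded. For HetTg against WT 5 of 35 splits gave as many genes (real 1, highest other 247). For CBE against PBS the 10 splits are too few for a share under 0.05 (real 5281, highest other 1). For the difference between models 5 of 100 relabellings gave as many (real 2841, highest other 3215). All 5 were among the 12 that kept or swapped the acute groups whole. Those 12 gave 2328 to 3215 genes with most of their chronic labels shuffled, and the highest with the acute groups mixed was 1. The count thus followed the acute groups, so it cannot test the chronic part of the difference.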

How the results depend on the processing

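The fits without the 3 shallowest libraries and with the GC content and length correction were chosen after seeing the data; the others were planned. No named gene called in a comparison changed direction in any alternative. Of the called genes named by the rule, 22 of 45 (KO against both controls), 2 of 10 (KO against HetTg), 10 of 10 (KO against WT), 1 of 1 (HetTg against WT), 127 of 138 (acute), 120 of 136 (age) and 98 of 125 (difference between models) kept their call in every alternative run. RLE scaling, limma-voom and both low-count filters kept each count of called genes within 1.5 times; the stricter filter removed no tested gene for age or the difference between models and tests nothing there, and it let in more genes than the default in the acute comparison (11162 against 10886), so it was not stricter there. Scaling moved the median of all genes by less than 0.1 on the log2 scale in each comparison.

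The counts of the chronic comparisons moved with the model. KO against both controls gave 217 genes; DESeq2 gave 423 (205 higher and 218 lower, against 132 and 85), all samples in one fit 656, the GC content and length correction 365, age in months as a covariate 106, and the fit without the 3 shallowest libraries 82. Taking the controls as 1 group gave 311 (155 higher, 156 lower). KO against HetTg gave 23 genes, with 67 in DESeq2, 61 with all samples in one fit and 13 with age as a covariate. KO against WT gave 230, with 414 in DESeq2, 624 with all samples in one fit, 147 with age as a covariate and 166 without the 3 shallowest libraries. HetTg against WT gave 1, with 2 in DESeq2. With each library left out in turn the ranges were 73 to 199, 5 to 22, 68 to 157 and 1 to 2 for these comparisons, 4513 to 5207 for CBE against PBS, 3196 to 4871 for age and 2108 to 3042 for the difference between models. Fewer samples enter the fits that leave libraries out; otherwise the cause was not tested.

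Gene lists called by camera numbered 13 (KO against both controls), 18 (acute), 6 (age) and 16 (difference between models). With an estimated correlation they numbered 4, 6, 0 and 6. For age, fry called 17 and the GC content and length correction 13. Leaving out each library gave 12 to 17, 18 to 18, 5 to 9 and 13 to 19 lists. The overlap of chronic and acute calls was 63 genes higher in both and 38 lower in both; at a threshold of 0.01 it was 22 and 3, the latter without a call (Fisher's exact test, p = 0.392), and at 0.10 it was 127 and 112, as fewer or more genes were called.

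The replicate numbers of the labels were tried as a replicate block, giving 134 genes for KO against both controls, 22 for KO against HetTg, 166 for KO against WT, 1 for HetTg against WT, 5115 for the acute comparison, 5180 for age and 2893 for the difference between models. Nothing in the labels says that a number marks a shared litter or day. Deviations of libraries with the same number correlated at -0.515 to 0.312 in the chronic model (3 of 10 pairs over 0.1), at -0.00632 to 0.0226 in the acute model and at 0.0189 to 0.0804 in the age table; 0, 2 and 6 libraries correlated best with their own number, so the numbers were not taken to pair the samples. Depth limits the HetTg group most, with 2 of its 3 libraries among the shallowest.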

Other observations

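The edgeR and camera tests behind these values were planned, but what is described in this part, and the genes not named in the report, were chosen after their values were seen. Some genes called in both models moved in opposite directions. Col6a1, a collagen chain, had a log2 fold change of 1.55 in KO against both controls and -0.78 in CBE against PBS, the noncoding 4933439C10Rik had 1.42 and -1.39, and Atoh7, a transcription factor of neural progenitors, had 0.91 and -1.60. In the other direction, Atf4 had -0.77 and 0.42 and Car2, a carbonic anhydrase, -0.70 and 0.95. The cold-inducible RNA-binding proteins Cirbp (1.30 and 0.66) and Rbm3 (1.32 and 1.95) were called higher in both models.

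For age 40.2% of all genes tested were called (edgeR), so called members alone do not set a list apart, and camera called none of the lists in this paragraph. Of 22 unfolded protein response genes 10 were higher and 2 lower in adult WT than in PBS mice (median 0.49, camera adjusted p = 0.0546). Of 19 cerebellar granule cell genes 8 were lower and 1 higher (median -0.22, camera adjusted p = 0.0546), and of 17 homeostatic microglia genes 5 were lower and 1 higher (median -0.31, camera adjusted p = 0.0885). Of 22 type I interferon genes 9 were higher and 2 lower (median 0.65, camera adjusted p = 0.0949). Of 5 erythrocyte transcripts 3 were lower (median -0.90, camera adjusted p = 0.0546).

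The acute and the age comparison share the PBS libraries. Their log2 fold changes had a covariance of 0.308 across genes, where 20 simulations of unchanged groups against those libraries averaged 0.0502, and a correlation of 0.504, where the simulations averaged 0.545. Each gene was drawn on its own in these simulations, without deviations shared between the genes of a library. How far such deviations could move these values was not simulated. Of 10482 genes tested in both, 1173 were higher in both where independent lists would give 507, and 1283 were lower in both where they would give 502. Comparisons that share controls are not independent lists, and these counts were not simulated. The PBS group is too small to be split into parts of at least 2 libraries, so how much of the excess comes from the shared controls is open.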
